A study of Danio rerio with 46 samples.

How the data were processed

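The data are 1-colour NimbleGen expression arrays of zebrafish, 46 in all: juvenile trunks at 37 dpf (8 control, 10 heat-exposed), adult testes (10 and 10) and adult ovaries (4 and 4) at 90 dpf. Per the labels' protocols, fish were exposed to 36 or 28 °C from 18 to 32 dpf and then reared at 28 °C, RNA was extracted with Trizol, amplified with a whole-transcriptome kit (NuGen Ovation V2) and labelled with Cy3. Per the series' design text the arrays are biological replicates. That text gives 10 juveniles per group, and the labels of the samples used here give 8 controls. The deposited values are on a log2 scale, made with RMA per the submitters' processing notes, a method that corrects background, normalizes by quantiles and summarizes probes to 1 value per row. The version of RMA, the array's annotation and which arrays were normalized together are not given in the sources used here. The log base is not written in the table either, and log2 was taken from the range of values, 3.76 to 15.89. Array upper quartiles lay close together within adults and within juveniles but differed between these ages, so levels were compared only within an age. Quantile normalization gives all arrays of a set a common distribution, which can hide a change that moves most genes one way and can shift unchanged genes when a large set falls. Whole-transcriptome amplification can compress or stretch differences between samples, and the labels' protocols name no correction for it. No labels of slide, scan or batch were given in the sources used here, so no batch could be tested.

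Rows are named as in the deposited table, with 15186 gene symbols and 16289 clone or locus style names. In a RefSeq gene table of the assembly GRCz12tu, used for names only, 14714 row names were current symbols and 3182 an older name of exactly 1 gene. Where the current symbol differs it is given in brackets at first mention or used in the text, as for vasa (ddx4), fos (fosab), hbba2, ifit8 and dnd (dnd1). The row named ddx41 is given under the table's name. Genes of near-identical copies, such as the zona pellucida and globin genes, may share hybridization, so a value for 1 member is uncertain by its relatives.

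All 46 arrays and all 31475 rows entered the tests, with no filter. Each heat comparison was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the log2 values of its own 2 temperature groups. The comparison of testis with ovary and the difference of the heat effect between them (an interaction contrast) came from 1 fit of the 28 adult arrays. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all rows, and a gene passed at an adjusted p under 0.05. Fold changes are differences of group means, heat-exposed minus control. Tests, lists of genes, the rule for named genes and most alternatives were fixed before the data were examined.

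The testis-minus-ovary index of an array is the mean log2 signal of the 500 rows most raised in testis minus that of the 500 most raised in ovary, by the sex contrast averaged over both temperatures among rows with an adjusted p under 0.05. Juveniles took no part in the choice of rows, while adult arrays did, so the index of adults is not independent of the choice. Group means were compared by a two-sided permutation test, exact where a group had under 10 arrays and with 100000 resamples otherwise, adjusted over 3 comparisons. List means were compared in the same way.

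The 27 lists held 1099 entries, of which 1017 were found, 95 of them by an older symbol, 82 were not found and 3 were dropped as repeats of a row within a list. The gonad lists were oocyte; ovarian follicle and estrogen; testis somatic and androgen; meiosis and spermatogenesis; and germ cell and piRNA. The stress and signaling lists were heat shock and chaperone; glucocorticoid and stress axis; DNA methylation and chromatin; apoptosis, p53 and DNA repair; Wnt signaling; NF-kB, prostaglandin and inflammation; and complement and interferon. Further lists were cell cycle; extracellular matrix; cholesterol and lipid synthesis; growth and thyroid; vitellogenin; and hypoxia and oxidative stress. Marker lists were those of liver, skeletal muscle, intestine, exocrine pancreas, kidney, erythrocytes, leukocytes, epidermis and neural tissue. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, which compares a list with all other genes. Camera with an estimated correlation, fry and the permutation test of list means were alternatives. Fry tests whether a list's genes move on balance one way and compares it with no other genes. Counts of members are given with p adjusted over all genes and adjusted over the list alone. The rule for named genes took, per heat comparison, the 10 genes that rose most and the 10 that fell most among those past the threshold with a gene symbol. It added up to 4 past the threshold in each list, and a panel of sex and stress genes. Where fewer than 10 passed, the 5 smallest p in each direction were added. The panel gene zp2.1 was not measured. Lists of eye, heart, forebrain and midbrain, and spinal cord and peripheral nerve genes were added after the data were seen.

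Alternatives, each changing 1 choice, were a repeated quantile normalization, a common 75th percentile, leaving out the dimmest 25% of rows, array weights and an intensity trend with a robust prior. Others were an adjusted p under 0.1, an absolute log2 fold change of at least 1, all arrays in 1 fit, the replicate number as a block, the oocyte list mean as a covariate, other sets of rows for the index, and each array left out in turn. Covariates of the neural and intestine lists, fits without arrays that stand apart and the permutation test of list means were added after the data were seen. The estimate of array weights stopped before its convergence tolerance was reached.

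The tests were checked on simulated data with 100 genes changed at each size among 31475. At a log2 change of 1, 54% of changed genes were recovered in the juvenile comparison, 0% in the ovary and 60% in the testis. At a log2 change of 2 the shares were 88%, 12% and 92%. For the difference between ovary and testis they were 9% and 54%, and for testis against ovary 26% and 80% in control and 25% and 75% in heat-exposed fish. Far fewer genes were changed than passed in the real juvenile comparison (4579) or between control testis and ovary (18199). Each simulated gene had the same spread in all groups, while the index of real ovaries had an SD of 0.13 in control and 4.28 in heat-exposed fish. These shares are therefore not the power of the real comparisons. In simulated lists a shifted oocyte list was called in each of the 3 heat comparisons, also with an estimated correlation, and 0, 0 and 1 of the other lists were called. Simulated genes were drawn independently of one another. In the real arrays the estimated correlation within the oocyte list was 0.72 in juveniles and 0.467 in ovaries. The simulation therefore cannot show how the list tests behave with correlated genes.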

Results

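Zebrafish were kept at 36 °C or at the control temperature of 28 °C from 18 to 32 days post fertilization (dpf), a period in which the zebrafish gonad takes on its sex, and were afterwards all reared at 28 °C. The series asks how this heat exposure alters gene expression in the gonad, soon after the exposure and in the adult. RNA was measured on 46 single-colour arrays with 31475 rows each. The juvenile groups held trunks of fish of unknown sex at 37 dpf, 8 from control fish and 10 from heat-exposed fish. The adult groups were gonads at 90 dpf: 10 control and 10 heat-exposed testes, and 4 control and 4 heat-exposed ovaries. Values are log2 signals, and the upper quartile of an array lay between 10.64 and 10.72 in adult gonads and between 10.90 and 10.95 in trunks. The number of arrays limits the precision, most of all in the ovary. Pairs of arrays within a group correlated across genes with a median r of 0.948 to 0.960 in 5 groups and of 0.821 in heat-exposed ovaries.

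The first comparison asked which genes differed in juvenile trunks after the exposure. The egg coat gene zp3.1 fell from 12.86 ± 2.09 (SD, n = 8) to 6.53 ± 1.28 (SD, n = 10), which is 80.4-fold (adjusted p = 4.6e-05). The germ cell helicase vasa (ddx4), which marks germ cells of both sexes, fell from 11.33 ± 1.49 to 7.67 ± 1.01 (adjusted p = 0.00031). Among single genes, hbbe2, gng3 and the early response gene fos (fosab) rose, and ifit8 and rsad2 fell. In limma, 2703 genes were higher and 1876 lower in heat-exposed trunks at an adjusted p under 0.05, 4579 of 31475 in all, and 1006 and 958 of them differed at least 2-fold.

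Of the 28 measured oocyte genes, 23 fell and 0 rose, and 25 fell and 1 rose when adjusted over the list alone. Among called genes with a gene symbol, the 10 that fell most were zp3.1 and 9 others, and rows with clone or locus style names were not ranked. Of the others, zp3a.1 (−6.30), zpcx (−6.03), zp2 (−5.85), zp2.2 (−5.84) and zp3a.2 (−5.37) encode egg coat proteins. With them fell h1m (−5.65), a linker histone of germ cells, btg4 (−6.12), a factor of maternal mRNA turnover, the claudin gene cldnd (−5.37) and the helicase gene ddx41 (−6.20). These are log2 fold changes, with adjusted p between 2.6e-05 and 0.000161. The egg coat gene zp3 of the oocyte list fell by 4.73. The list had a median log2 fold change of −4.24, and its mean signal was 11.12 ± 1.70 (SD, n = 8) in control and 7.58 ± 0.57 (n = 10) in heat-exposed trunks. The shift of the list had an adjusted p of 5.15e-25 in limma's camera, and an adjusted p = 0.233 with an estimated correlation. Control trunks differed much among themselves, with oocyte list means of 12.33, 8.51, 11.98, 8.58, 12.53, 10.56, 12.20 and 12.28 in arrays 1 to 8. Of 26 germ cell and piRNA genes, 19 fell and 2 rose (21 and 2 when adjusted over the list alone), with a median of −2.20. The adjusted p was 2.51e-14, against an adjusted p = 0.233 with an estimated correlation. Among them were ca15b (−4.66), the germ cell RNA-binding gene dnd (dnd1; −4.09) and asz1 (−2.97), a gene of the piRNA pathway.

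**Figure D1:**
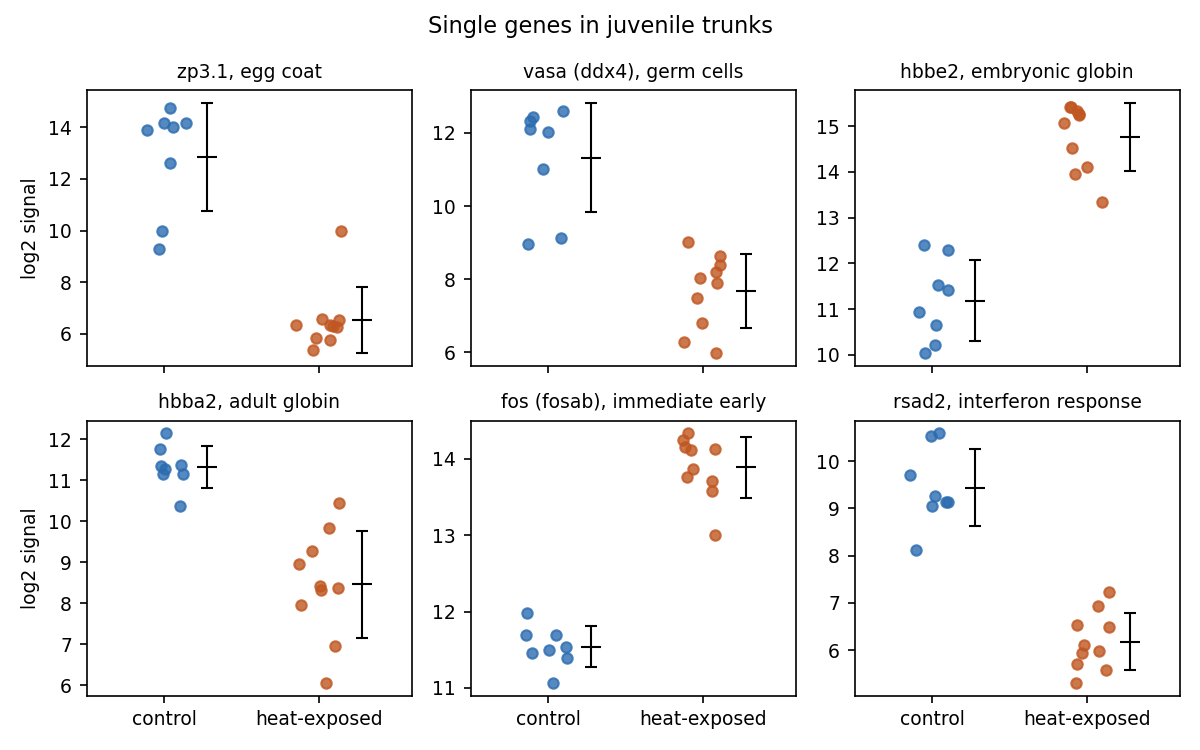
Log2 signal of 6 genes in each juvenile trunk (points; 8 control and 10 heat-exposed arrays), with group mean and SD beside the points. zp3.1, vasa, hbba2 and rsad2 were lower and hbbe2 and fos higher after heat, and the signal of zp3.1 in heat-exposed trunk 1 was 10.00, above the other heat-exposed trunks.

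Of 50 genes of meiosis and spermatogenesis, 21 rose, 6 fell and 23 did not pass (25 rose and 8 fell when adjusted over the list alone), with a median of 0.62. In the same trunks the neural list rose with a median of 0.71, and its call ended with an estimated correlation (adjusted p = 0.477). The adjusted p of the meiosis and spermatogenesis list was 9.57e-05, against an adjusted p = 0.458 with an estimated correlation. The sperm flagellum gene tekt3 rose by 1.93 and tbata by 2.34 on the log2 scale. The gene meig1 rose by 1.32 (adjusted p = 1.65e-05), and hormad1, a protein of meiotic chromosomes, fell by 1.68. To follow sex-biased genes in the trunks, an index was formed from the 500 rows most raised in adult testis minus the 500 most raised in adult ovary, chosen without the juveniles. It was −2.51 ± 1.17 (SD, n = 8) in control and 0.04 ± 0.23 (n = 10) in heat-exposed trunks, a difference of 2.55. The test gave the smallest p this design allows (two-sided exact permutation p = 2.29e-05; 6.87e-05 adjusted over 3 comparisons). Control trunks ranged from −3.71 to −0.79 and heat-exposed trunks from −0.53 to 0.32. Most of the difference came from the ovary-raised rows, whose mean fell from 9.62 ± 1.18 to 7.41 ± 0.23, while the mean of the testis-raised rows rose from 7.12 ± 0.06 to 7.45 ± 0.17 (exact permutation p = 9.14e-05). In control adults, testis-raised rows averaged 12.81 in testes and 6.61 in ovaries, and ovary-raised rows 12.53 in ovaries and 7.16 in testes. Levels were not tested across ages. Both sets were thus low in heat-exposed trunks, and an index near 0 does not place a trunk midway between ovary and testis.

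**Figure D2:**
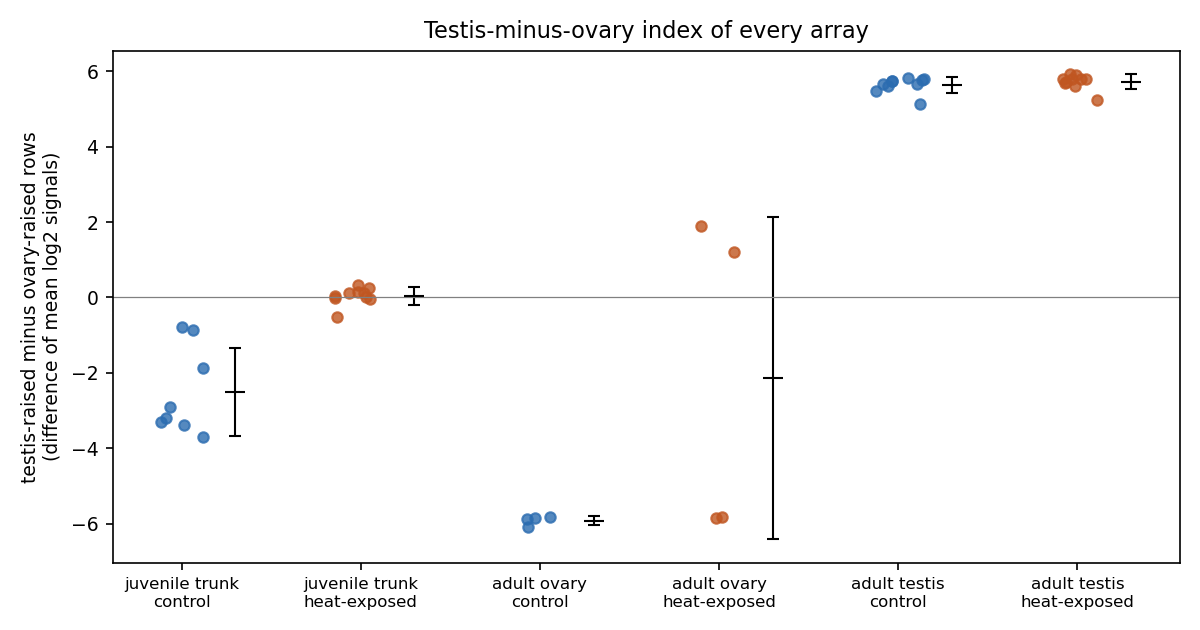
Testis-minus-ovary index (difference of mean log2 signals) of each of the 46 arrays by group, with mean and SD beside the points. Heat-exposed trunks lay above control trunks, and heat-exposed ovaries 2 and 4 lay at 1.90 and 1.21 while the other heat-exposed ovaries lay at −5.85 and −5.84.

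In the list of ovarian follicle and estrogen genes, 3 of 28 rose and 2 fell (3 and 3 when adjusted over the list alone), and the list's adjusted p of 0.05 after rounding did not pass in camera, against 0.0169 in fry and 0.028 in the permutation test of the list mean. The estrogen receptor genes esr2b (−1.68, adjusted p = 4.53e-05) and esr2a (−1.32) fell, and the ligand gene wnt4b (1.47) and the gonadal transcription factor gene lhx9 (1.25) rose. Of 29 testis somatic and androgen genes, 5 fell and 2 rose (8 and 3 when adjusted over the list alone; list adjusted p = 0.0671 in camera, 0.0169 in fry and 0.000926 in the permutation test). Among them were cyp11a1 (cyp11a1.1; −3.16, adjusted p = 0.00163), the side-chain cleavage enzyme of steroid synthesis, the androgen receptor gene ar (−0.50) and sox9a (0.48, adjusted p = 0.0126). In the fixed panel of sex genes, the oocyte growth factor gene gdf9 also fell (−2.58, adjusted p = 0.001). The aromatase gene cyp19a1a (−0.60, adjusted p = 0.217), foxl2 (foxl2a; 0.45, adjusted p = 0.312) and gsdf (−0.98, adjusted p = 0.0595) did not pass. Nor did dmrt1 (−0.38, adjusted p = 0.0683), amh (0.06, adjusted p = 0.885), cyp11c1 (0.56, adjusted p = 0.186) or sycp3 (−0.16, adjusted p = 0.681). The same held for vtg1 (0.26, adjusted p = 0.449), the heat shock genes hsp70l (0.62, adjusted p = 0.354) and hsp90aa1.1 (−0.01, adjusted p = 0.978) and the methyltransferase gene dnmt1 (−0.32, adjusted p = 0.311).

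Of 41 neural marker genes, 21 rose and 2 fell (27 and 3 when adjusted over the list alone), with a median of 0.71. The adjusted p was 5.06e-06, against an adjusted p = 0.477 with an estimated correlation. The neuronal genes gng3 (1.39), rtn1b (1.39) and gap43 (0.83) rose, while mpz, a protein of myelin, fell by 1.05. Against the control mean, the list stood 1.5, 0.59, 1.02, 0.45, 0.84, 0.17, 0.20, 0.06, 0.45 and 1.13 higher in heat-exposed trunks 1 to 10. Among the 10 called genes with a gene symbol that rose most were npas4a (3.14), a transcription factor gene of active neurons, and epd (3.21), which encodes a secreted protein of the brain. Others of the 10 were the ammonia transporter gene rhcga (3.58), gcm2 (3.33), fgf19 (3.38), bricd5 (3.65) and foxq1a (2.89, adjusted p = 6.38e-06). The erythrocyte list as a whole did not pass (adjusted p = 0.839; median −0.01, mean 0.25), yet 4 of its 27 genes rose and 3 fell, the same numbers when adjusted over the list alone. The embryonic globin genes hbbe2 (11.19 ± 0.88 to 14.77 ± 0.74, adjusted p = 9.15e-06), hbae1 (hbae1.1; 3.01), hbbe1.1 (2.69) and hbae3 (4.95) rose, and the adult globin gene hbba2 fell by 2.87 (adjusted p = 0.000495).

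In the complement and interferon list, 9 of 44 fell, 2 rose and 33 did not pass (the same numbers when adjusted over the list alone), with a median of −0.14. The adjusted p was 0.000515, against an adjusted p = 0.509 with an estimated correlation. The antiviral genes ifit8 (10.92 ± 0.62 to 6.71 ± 0.64, adjusted p = 4.05e-08), rsad2 (−3.26), mxe (−1.93) and isg15 (−1.64) fell. Of 53 cell cycle genes, 15 fell and 0 rose (17 and 1 when adjusted over the list alone). Among them were birc5b (−4.64), ccnb2 (−2.22), aurka (−2.11) and ccna2 (−1.56). The list had a median of −0.35 and an adjusted p of 4.35e-06, against an adjusted p = 0.545 with an estimated correlation. The list mean went with that of the oocyte list among controls: it was 10.38, 10.37 and 10.54 in control trunks 2, 4 and 6, which were lowest in the oocyte list, and 11.05 to 11.46 in the other controls, where heat-exposed trunks averaged 10.42. Of 45 cholesterol and lipid synthesis genes, 6 fell and 0 rose (the same numbers when adjusted over the list alone). The list had a median of −0.31, an adjusted p of 4.15e-05 and an adjusted p = 0.458 with an estimated correlation. Against the control mean, the list stood at −1.08 and −0.97 in heat-exposed trunks 1 and 10 and at −0.03, 0.03 and −0.05 in 7, 8 and 9. The genes that fell included the triglyceride synthesis genes dgat1a (−1.18) and dgat2 (−0.71) and the fatty acid synthesis gene acaca (−1.11).

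Of 41 NF-kB, prostaglandin and inflammation genes, 12 rose and 0 fell (15 and 3 when adjusted over the list alone), with a median of 0.14. The adjusted p was 0.0302, against an adjusted p = 0.575 with an estimated correlation. Control trunk 2 had a list mean of 10.29, where the other controls ranged from 9.39 to 9.68 and heat-exposed trunks averaged 9.99. The early response gene fos rose from 11.54 ± 0.27 (SD, n = 8) to 13.89 ± 0.40 (SD, n = 10; adjusted p = 8.57e-08), and ptgs2b (2.09), which encodes a cyclooxygenase of prostaglandin synthesis, junba (1.59) and cebpb (0.88) rose. Of 61 Wnt signaling genes, 15 rose and 3 fell (16 and 7 when adjusted over the list alone), with a median of 0.18. The adjusted p was 0.0331, against an adjusted p = 0.458 with an estimated correlation. The secreted Wnt inhibitor genes dkk1b (1.71) and sfrp5 (0.92) and the receptor gene fzd7a (0.63) rose. The NF-kB call ended without control trunk 4 (adjusted p = 0.0542), 7 (0.0531) or 8 (0.0549). The Wnt call ended without control trunk 1 (0.0539), 6 (0.0632) or 8 (0.0615) or heat-exposed trunk 1 (0.0569) or 9 (0.0502).

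**Figure D3:**
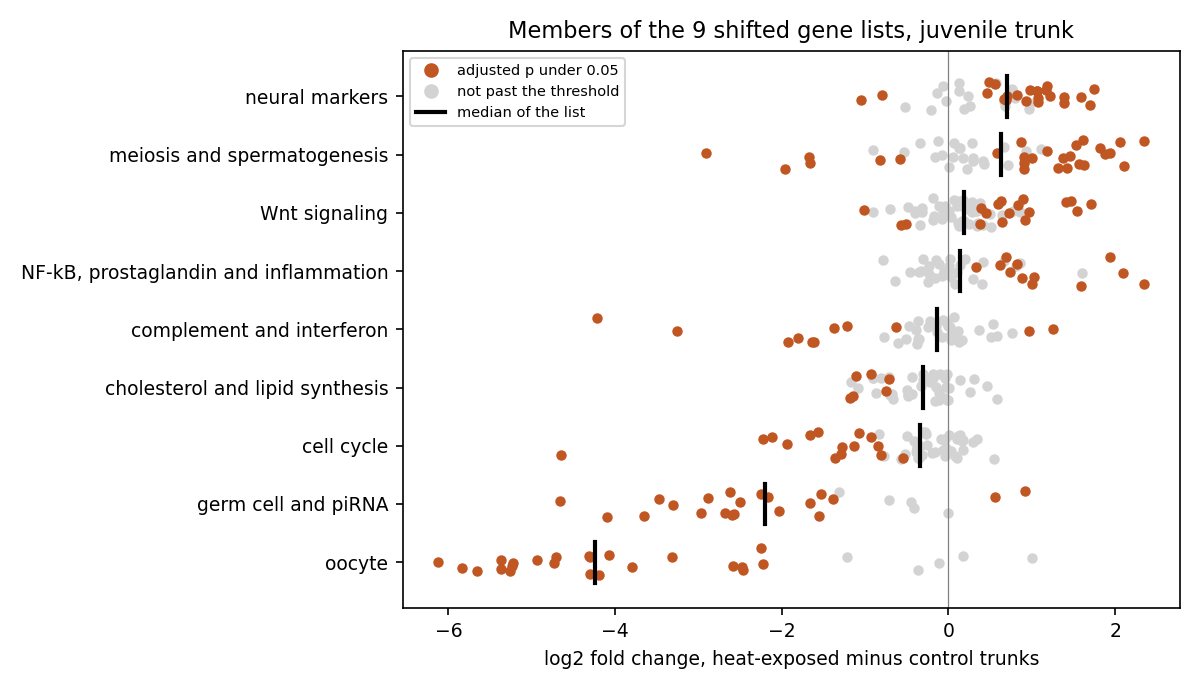
Log2 fold change (heat-exposed minus control trunks) of each member of the 9 lists that passed in juveniles, with members at an adjusted p under 0.05 in colour and the list median as a bar. The oocyte list had a median of −4.24 and the neural list of 0.71.

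The remaining lists did not pass in juveniles. Of the pathway lists these were heat shock and chaperone (adjusted p = 0.767; 3 of 62 rose and 1 fell), glucocorticoid and stress axis (0.362; 1 of 26 rose, 4 fell), and DNA methylation and chromatin (0.177; 2 of 48 rose, 2 fell). They were also apoptosis, p53 and DNA repair (0.839; 5 of 52 rose, 1 fell), extracellular matrix (0.087; 5 of 53 rose, 6 fell), and growth and thyroid (0.256; 2 of 40 rose, 5 fell). The same held for vitellogenin (0.476; 0 of 7 rose, 1 fell) and hypoxia and oxidative stress (0.839; 3 of 47 rose, 0 fell). It held too for the markers of liver (0.839), skeletal muscle (0.256), intestine (0.0848), exocrine pancreas (0.447), kidney (0.415), leukocytes (0.839) and epidermis (0.839). Median, mean and test differed in sign in the heat shock, apoptosis, growth, vitellogenin, hypoxia and erythrocyte lists, none of which passed. Across all 27 lists, 9 passed in camera and 0 with an estimated correlation. In limma's fry, which asks whether a list's genes move on balance one way, 9 passed. The calls of the cell cycle (adjusted p = 0.154) and cholesterol (0.0682) lists ended there, and the ovarian follicle and testis somatic lists passed. In a permutation test of the list mean 12 passed, the 9 of camera and those of ovarian follicle, testis somatic, and DNA methylation and chromatin genes (the last with an adjusted p of 0.028). The count of genes was 345 with the oocyte list mean as a covariate, 954 with the neural list mean and 2863 without heat-exposed trunks 1, 2 and 10, which stood apart on principal components. The last 2 of these were chosen after the data were seen. The covariates themselves differed between control and heat-exposed trunks, from 11.12 to 7.58 for the oocyte list mean and from 9.92 to 10.57 for the neural list mean. They therefore take up part of the heat effect whatever its cause, and the lower counts cannot show what accounts for the genes.

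The next comparison asked which genes differed in adult ovaries of fish exposed as juveniles. Heat-exposed ovaries 2 and 4 carried many testis transcripts, and heat-exposed ovaries 1 and 3 did not. The index was −5.92 ± 0.13 (SD, n = 4) in control ovaries and −5.85, 1.90, −5.84 and 1.21 in heat-exposed ovaries 1 to 4, where control testes averaged 5.65. The mean of the meiosis and spermatogenesis list stood 0.01, 3.30, 0.16 and 3.42 above the control mean in the same ovaries, and the mean of the oocyte list stood at 0.04, −1.32, 0.07 and −0.93. The difference in index between the groups, 3.78, had a two-sided exact permutation p of 0.0857 (0.129 adjusted over 3 comparisons), where the smallest p this design allows is 0.0286. With rows chosen in control fish alone the difference was 4.04 and its adjusted p 0.0429. Such rows are picked for being extreme in the control ovaries, which favours a difference, so this p cannot decide.

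No gene passed: limma called 0 of 31475 genes at an adjusted p under 0.05, with 3334 at an unadjusted p under 0.05 and a smallest adjusted p of 0.106. With array weights 4 genes passed, with all 46 arrays in 1 model 4869, and without heat-exposed ovaries 2 and 4 (chosen after the data were seen) 8. Leaving out single arrays gave 2 genes without heat-exposed ovary 1, 1 without 2 and 5 without 3. Among genes with a gene symbol, the smallest p-values of lower genes belonged to dusp4, a phosphatase of MAP kinases (11.94 ± 0.24 to 8.20 ± 0.70, SD, n = 4 each; adjusted p = 0.106) and the neuropeptide gene kiss1 (−3.94, adjusted p = 0.106). Next came ntla (tbxta; −2.00, adjusted p = 0.13), the bile salt transporter gene abcb11b (−2.99, adjusted p = 0.2) and gabrb2l (−1.55, adjusted p = 0.2). Those of higher genes belonged to ndufs8b, a subunit of mitochondrial complex I (4.87 ± 0.19 to 10.78 ± 1.68, adjusted p = 0.13) and pfkfb2 (pfkfb2a), a regulator of glycolysis (3.01, adjusted p = 0.2). Next were ecscr (1.81, adjusted p = 0.269), atraid (1.98, adjusted p = 0.351) and barhl1b (1.91, adjusted p = 0.351). Without heat-exposed ovary 3, dusp4 (adjusted p = 0.0205) and kiss1 (0.0423) passed, as did ndufs8b without heat-exposed ovary 2 (0.00579). The panel held the testis-biased genes cyp11c1 (3.1), amh (2.43), sycp3 (2.3), gsdf (1.34) and dmrt1 (1.08) and the ovary-biased genes cyp19a1a (−1.85), foxl2 (−1.39) and gdf9 (−1.30). Their means pool the unlike heat-exposed ovaries 1 and 3 with 2 and 4, over which the SD ran from 0.83 (dmrt1) to 2.65 (cyp11c1). These genes had adjusted p of 0.434 to 0.471. vasa (0.28), vtg1 (0.46), hsp70l (−0.05), hsp90aa1.1 (0.33), dnmt1 (−0.55) and sox9a (−0.07) did not pass either.

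Of the 27 lists, 13 passed in camera with its preset correlation, 11 higher and 2 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.467), in fry, or in an exact permutation test of list means. The smallest p that this permutation test allows with 4 against 4 ovaries is 0.0286. Lists at that p, such as extracellular matrix, had an adjusted p of 0.193. The permutation test could therefore hardly pass a list and does not count against the calls. The exocrine pancreas markers moved most, with a median of 2.68 and an adjusted p of 4.93e-11 (adjusted p = 0.467 with an estimated correlation); 0 of 18 passed over all genes and 15 rose when adjusted over the list alone. They stood 2.37, 2.3, 1.90 and 2.93 above the control mean in heat-exposed ovaries 1 to 4, and at −0.27, 1.99, −0.82 and −0.89 in control ovaries 1 to 4. In the other 12 lists 0 genes passed over all genes and 0 when adjusted over the list alone. Higher were meiosis and spermatogenesis (median 1.81, adjusted p = 1.26e-09), erythrocyte markers (1.24, 2.2e-05), liver markers (0.92, 4.34e-05), extracellular matrix (0.67, 9.23e-05) and complement and interferon (0.79, 0.000497). So were neural markers (0.42, 0.00202), intestine markers (0.58, 0.0104) and glucocorticoid genes (0.50, 0.0114). Each of these 8 lists had an adjusted p = 0.467 with an estimated correlation. Also higher were leukocyte markers (0.54, 0.00404) and kidney markers (0.37, 0.0224), each with an adjusted p = 0.558 with an estimated correlation. Lower were the oocyte list (−0.51, 0.00202; adjusted p = 0.558 with an estimated correlation) and DNA methylation and chromatin (−0.39, 0.0396; adjusted p = 0.518 with an estimated correlation). In each of these 12 lists, heat-exposed ovaries 2 and 4 lay further from the control mean than 1 and 3. Erythrocyte markers stood 0.29, 2.35, 0.26 and 1.85 above it in heat-exposed ovaries 1 to 4. Control testes differed from control ovaries in the same direction in each list, as with 9.57 against 8.39 for erythrocyte markers. How far testis transcripts in ovaries 2 and 4 account for these shifts was not tested.

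**Figure D4:**
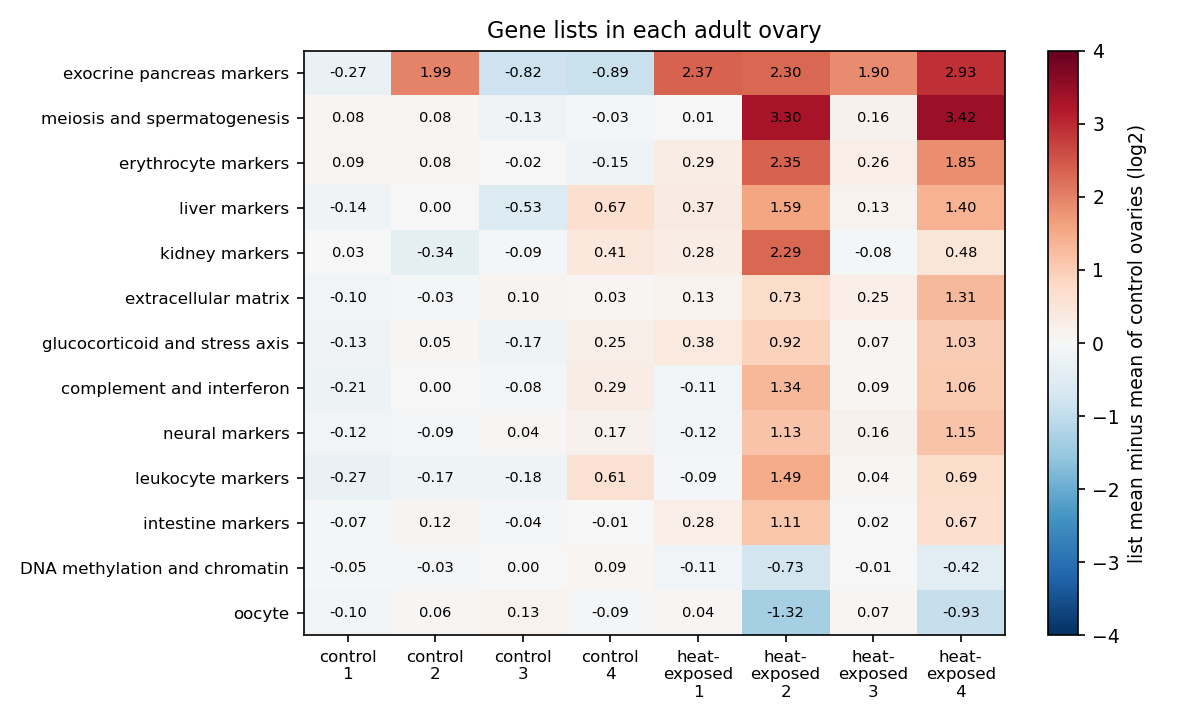
Mean log2 signal of the 13 lists that passed in ovaries, in each of the 8 ovaries (columns), minus the mean of the 4 control ovaries. The meiosis and spermatogenesis list stood at 3.30 and 3.42 in heat-exposed ovaries 2 and 4 and at 0.01 and 0.16 in heat-exposed ovaries 1 and 3, while the exocrine pancreas list was at least 1.90 in all heat-exposed ovaries and 1.99 in control ovary 2.

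Without heat-exposed ovaries 2 and 4, 2 lists passed, both higher, the pancreas markers (adjusted p = 8.6e-10) and vitellogenin (0.00594). Over all arrays the vitellogenin list was lower without passing (median −0.29): it stood 0.82 and 0.43 above the control mean in heat-exposed ovaries 1 and 3 and at −1.02 and −1.42 in 2 and 4. Without heat-exposed ovary 2 alone, the calls of the kidney (adjusted p = 0.595), leukocyte (0.0898), intestine (0.0867) and DNA methylation (0.0957) lists ended. The DNA methylation call also ended without control ovary 3 (0.0555) or 4 (0.075), the kidney call without control ovary 2 (0.0518) or 3 (0.0555), and the glucocorticoid call without control ovary 3 (0.0555). The lists of ovarian follicle (adjusted p = 0.0911), testis somatic (0.0802), germ cell (0.0866), heat shock (0.644), apoptosis (0.538), Wnt (0.766) and NF-kB (0.647) genes did not pass. Nor did those of cell cycle (0.075), cholesterol (0.57), growth (0.116), vitellogenin (0.584), hypoxia (0.765), skeletal muscle (0.0806) and epidermis (0.0564) genes. Median, mean and test differed in sign in the Wnt, cholesterol and hypoxia lists.

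The same question was asked of adult testes, where few genes differed. The gene slc25a32a, a mitochondrial folate carrier, rose from 10.69 ± 0.23 to 11.52 ± 0.13 (SD, n = 10 each; adjusted p = 0.00264). The neutrophil-linked chemotaxin gene lect2l rose from 8.92 ± 0.71 to 11.62 ± 1.39 (6.53-fold, adjusted p = 0.0359). Limma called 20 genes, 17 higher and 3 lower. Those with gene symbols also included afap1l2 (1.28), an adaptor of actin filaments, gdpd2 (0.86) and enosf1 (0.80), each with an adjusted p of 0.0237. At an adjusted p of 0.0436 followed agtrap (1.47), the Toll-like receptor gene tlr20a (tlr20.2; 0.94), clec16a (0.62), pdcd8 (aifm1; −0.85), an apoptosis-inducing factor, and the cell cycle transcription factor gene e2f2 (−0.66).

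No gene of the panel passed in testes: cyp19a1a (−0.06, adjusted p = 0.933), foxl2 (−0.28), gsdf (−0.09), dmrt1 (−0.10), amh (0.10) and sox9a (0.25, adjusted p = 0.424). The others were cyp11c1 (−0.39, adjusted p = 0.536), vasa (−0.53, adjusted p = 0.377), gdf9 (0.14), sycp3 (−0.09), vtg1 (−0.12), hsp70l (0.07), hsp90aa1.1 (−0.35) and dnmt1 (0.15). The index was 5.65 ± 0.21 in control and 5.73 ± 0.19 in heat-exposed testes (SD, n = 10 each; permutation p = 0.364). With rows chosen in heat-exposed fish alone the difference was 0.22 and its adjusted p 0.0212. Such rows are picked for being extreme in the heat-exposed testes, which favours a difference, so this p cannot decide.

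Of the 27 lists, 10 passed in testes, 4 higher and 6 lower. In fry 5 passed, those of heat shock, germ cell, leukocyte, erythrocyte and kidney genes, and in a permutation test of the list mean 4, the same without erythrocyte markers (adjusted p = 0.0886). Heat shock and chaperone genes were lower, with a median of −0.12, an adjusted p of 0.000186 and an adjusted p = 0.0147 with an estimated correlation; 0 of 62 passed over all genes and 1 fell when adjusted over the list alone. No other list kept its call with an estimated correlation. Leukocyte markers had a median of 0.37 and an adjusted p of 1.06e-05 (adjusted p = 0.13 with an estimated correlation); 1 of 45, lect2l, rose, and 16 rose and 1 fell when adjusted over the list alone. Erythrocyte markers had a median of 0.48 and an adjusted p of 1.06e-05 (adjusted p = 0.158 with an estimated correlation), with 0 of 27 past over all genes and 8 rising and 2 falling when adjusted over the list alone. Kidney markers had a median of 0.26 and an adjusted p of 3.09e-05 (adjusted p = 0.059 with an estimated correlation), with 0 of 20 past over all genes and 5 rising when adjusted over the list alone. Intestine markers had a median of 0.35 and an adjusted p of 0.00392 (adjusted p = 0.47 with an estimated correlation), and the call ended without heat-exposed testis 8 (adjusted p = 0.0821), whose list mean was 9.64 where the other heat-exposed testes ranged from 7.38 to 8.28.

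Lower beside heat shock genes were germ cell and piRNA genes (median −0.27, adjusted p = 0.000352; adjusted p = 0.059 with an estimated correlation), of which 1 of 26 fell when adjusted over the list alone, and cell cycle genes (−0.11, 0.000406; adjusted p = 0.304 with an estimated correlation). Exocrine pancreas markers (−0.54, 0.000474; adjusted p = 0.499 with an estimated correlation), skeletal muscle markers (−0.24, 0.00119; adjusted p = 0.535 with an estimated correlation) and vitellogenin genes (−0.30, 0.0111; adjusted p = 0.304 with an estimated correlation) were lower too. In these 5 lists 0 genes passed over all genes, and of 40 muscle markers 1 fell when adjusted over the list alone. Among lists that did not pass were oocyte (adjusted p = 0.763), ovarian follicle (0.343), testis somatic (0.0728), meiosis and spermatogenesis (0.763), glucocorticoid (0.695), DNA methylation (0.0596), apoptosis (0.362) and Wnt (0.905) genes. Others were the NF-kB (0.695), complement and interferon (0.362), extracellular matrix (0.695), cholesterol (0.125), growth (0.905), hypoxia (0.695), liver (0.905), epidermis (0.618) and neural (0.695) genes. Median, mean and test differed in sign in the oocyte, meiosis, complement, Wnt, growth, liver and neural lists.

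The count of genes in testes depended on nearly every array. It changed by more than 1.5 times in 18 of the 20 fits that left out 1 array. Without control testis 1 to 10 in turn it was 12, 5, 2, 5, 57, 1, 7, 10, 6 and 9, and without heat-exposed testis 1 to 10 it was 9, 24, 26, 8, 13, 6, 8, 8, 47 and 8. The call of slc25a32a held in all 20 of these, that of enosf1 ended without control testis 6 (adjusted p = 0.057), and those of afap1l2 and gdpd2 ended without control testis 3 (0.0509 for each) or 6 (0.057 for each). The calls of lect2l, agtrap, tlr20a, clec16a, pdcd8 and e2f2 ended in 13, 16, 17, 17, 16 and 16 of the 20. Without heat-exposed testes 8 and 10, which stood apart on the first principal component, 2 genes passed, and with the intestine list mean as a covariate 1 passed, both chosen after the data were seen.

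Testis and ovary themselves were compared at each temperature. At the control temperature 18199 genes differed, 8895 higher in testis and 9304 higher in ovary, and in heat-exposed fish 12268 differed, 6532 and 5736. In control fish the androgen synthesis gene cyp11c1 (6.60 ± 0.19, n = 4, against 12.52 ± 0.26, n = 10; adjusted p = 4.19e-09), amh (4.71 higher in testis), gsdf (3.66), dmrt1 (2.65) and the synaptonemal complex gene sycp3 (4.74) were higher in testis on the log2 scale. So were hsp70l (0.77) and hsp90aa1.1 (1.33). Testis minus ovary was −4.18 for the aromatase gene cyp19a1a (adjusted p = 1.37e-08), −2.29 for foxl2 (0.00286), −3.41 for gdf9 (3.79e-06) and −1.33 for dnmt1 (2.62e-06). The differences for vasa (0.32, adjusted p = 0.35), sox9a (−0.29, 0.122) and vtg1 (−0.05, 0.889) did not pass. In heat-exposed fish the difference was −2.39 for cyp19a1a, 2.44 for cyp11c1, 2.38 for amh, 2.35 for sycp3 and −1.18 for foxl2, and the last did not pass (adjusted p = 0.142). Without heat-exposed ovary 1, 7848 genes differed in heat-exposed fish, and without heat-exposed ovary 2, 14212 did. The means of heat-exposed ovaries pool ovaries 1 and 3 (index −5.85 and −5.84) with the unlike ovaries 2 and 4 (1.90 and 1.21). Over these ovaries the SD of the genes named for heat-exposed fish ran from 1.755 (amh) to 2.65 (cyp11c1). The smaller differences therefore cannot be read as holding in each heat-exposed ovary.

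Whether heat acted differently in ovary and testis was tested as the ovary effect minus the testis effect. In limma 380 genes passed, 227 with a positive and 153 with a negative difference. They included dusp4 (−3.23, adjusted p = 0.000119), pfkfb2 (2.94, 0.00078), kiss1 (−3.84, 0.00177), slc25a32a (−1.51, 0.00163) and, in the panel, cyp11c1 (3.49, 0.0392). The count moved with the heat-exposed ovaries: it was 4817, 50, 4398 and 48 without heat-exposed ovary 1, 2, 3 and 4 in turn, and 122 to 236 without 1 at a time of 19 other arrays that moved it by more than 1.5 times. The heat effect on the index was larger in juveniles than in testes by 2.46 (permutation p = 7e-05, adjusted 0.00021). Between juveniles and ovaries the difference was −1.23 (permutation p = 0.481), and between ovaries and testes it was 3.69 (permutation p = 0.267, adjusted 0.4). Testes lay at the testis end of the index (5.14 to 5.93), whose rows were chosen partly on them. A shift towards testis had little room to show there, which limits both comparisons with testes.

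Across genes, which are not independent replicates, the heat effects of juveniles and ovaries had a Pearson r of 0.182 and a Spearman rho of 0.207, those of juveniles and testes 0.0553 and 0.0444, and those of ovaries and testes 0.0790 and 0.0928. Juveniles and testes shared 4 called genes, 2 of them with the same direction, where 2.91 would be shared by independent lists. The ovary called none, so no overlap could be formed with it.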

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

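The tests of mixed RNA, exchanged arrays, a wrong label, diluted gonad, less gonad and eye tissue were chosen after the result was seen, and the bound of the test of less gonad was rewritten after its value was known. The predictions for counts of other splits were written before. Those for head tissue and trunk nerve were written before the values of their own lists were known, but these lists were added after the data were seen. Of 408 groups of values tested for a single array far from the others (its gap to the nearest array over the group's range), 38 held such an array where chance gives about 1 in 20, which is 20.4.

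In heat-exposed juvenile trunks, array 1 stood high for zp3.1 (ratio 0.740; 10.00 against 5.36 to 6.56 in the others), zp3a.1 (0.577), ddx41 (0.576), btg4 (0.654), zpcx (0.533), zp2 (0.514), zp2.2 (0.47), zp3a.2 (0.495), cldnd (0.536), zp3 (0.489) and ca15b (0.577), and low for the index (0.561; −0.53). Array 8 was low for bricd5 (0.634; 5.59 against 9.93 to 12.45), gcm2 (0.479) and epd (0.587), and it also had the lowest neural list mean among heat-exposed trunks. Array 10 was low for dnmt1 (0.496). Among control trunks, array 2 stood apart in the NF-kB list (0.678; 10.29 against 9.39 to 9.68), junba (0.566), cbx7a (0.579), lhx9 (0.585) and cyp11c1 (0.605), array 4 in gsdf (0.573) and array 1 in hsp90aa1.1 (0.808; 13.69 against 14.22 to 14.34).

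Among ovaries, control 4 stood apart in the leukocyte list (0.893) and in vasa (0.851), control 3 in atraid (0.913), and heat-exposed ovary 4 in atraid (0.840) and abcb11b (0.928). Among control testes, array 7 was low in the index (0.50; 5.14), array 5 in the cell cycle list (0.525) and array 1 high in cyp19a1a (0.507). Among heat-exposed testes, array 10 was low in the index (0.538; 5.25), in the germ cell list (0.594), in cyp11c1 (0.676) and in vasa (0.685), array 8 was high in the intestine list (0.601), array 2 in clec16a (0.492) and array 3 in sox9a (0.529).

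The heat effect differed between ovary and testis by limma's interaction contrast in 380 genes, and among named genes in pfkfb2 (2.94), atraid (2.0), dusp4 (−3.23), kiss1 (−3.84), ntla (−1.93), abcb11b (−2.78), cyp11c1 (3.49), agtrap (−1.97), slc25a32a (−1.51) and clec16a (−1.03). The index effect differed between juveniles and testes by 2.46. The count of 380 was 4817, 50, 4398 and 48 without heat-exposed ovary 1, 2, 3 and 4 in turn, and 122 to 236 without 1 of 19 other arrays at a time and 254 to 472 without 1 of the remaining 5. Chance could not be excluded for it, since 9 of 100 splits of the arrays within each tissue gave as many, the highest other split 706. That other splits call more genes may reflect a structure among the samples. Whether heat-exposed ovaries 2 and 4 account for it was not tested, since the grouping of arrays in those splits was not examined.

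For the other counts, only the real split gave as many as the 4579 juvenile genes (1 of 100 splits, highest other 2) and the 20 testis genes (1 of 100, highest other 1). With 100 splits the share cannot be smaller, so chance was made unlikely there and was not excluded. The same held for the 18199 genes between testis and ovary at control temperature (1 of 100, highest other 10390) and the 12268 in heat-exposed fish (1 of 100, highest other 10145). Those splits mixed 2 organs, so their outcome was largely fixed beforehand. Other splits also reached the counts of lists in juveniles (9 lists; 33 of 100 splits, highest other 12), ovaries (13 lists; 11 of 35, highest other 16) and testes (10 lists; 6 of 100, highest other 11), so chance stays open for these. The ovary's count of 0 in limma is reached by every split (35 of 35, highest other 5), so the splits decide nothing there. In that comparison 3334 genes had an unadjusted p under 0.05, array weights gave 4 and all arrays in 1 fit 4869.

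Heat-exposed ovaries 2 and 4 lay between ovary and testis. Shares of the mean control testis and ovary were estimated separately and were not made to add up to the whole. They were 65.3% testis and 14.8% ovary for array 2 and 62.3% and 23.7% for array 4. Their sums were 80.1% and 86.0%, against 96.1% to 102.2% in control ovaries. In heat-exposed ovaries 1 and 3 the sums were 96.8% and 99.0%. Whether mixed RNA would give sums as low as those of arrays 2 and 4 was not tested. An exchange of ovary and testis arrays is argued against, since 0 testis arrays had an index under 0. A normal testis under an ovary label is argued against for both arrays: their lowest oocyte list mean, 11.55, lay 1.561 above the highest of 20 testes (SD 0.211), and their index of 1.90 and 1.21 lay under the 5.14 to 5.93 of the testes. RNA of a normal testis mixed into a normal ovary should give few rows beyond all control gonads. In array 4, 41 rows lay more than 2-fold above the highest control gonad. Control ovaries set against the other controls gave 102 to 254 such rows, so by this test alone mixing may hold for array 4. Array 2 gave 486 such rows, among them 7 of 20 kidney markers and 9 of 45 leukocyte markers (lect2l at 14.18, against 9.91 in the highest control), and since RNA of a further tissue could add these rows, mixing cannot be told apart from other explanations there. A gonad in passage from ovary to testis after heat stays open and was not tested.

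In juveniles the oocyte genes fell while testis-raised rows rose. Dilution of the gonad by head tissue is argued against: in the 3 heat-exposed trunks with the lowest neural list mean the highest oocyte list mean was 7.22, below the lowest control at 8.51. Less gonad of either sex could lower oocyte genes, and germ cell list members within 2-fold between adult testis and ovary had a median change of −1.66 (15 genes, of which 10 fell and 2 rose). The testis-raised rows were 0.24 higher with the neural list mean held fixed, where 0 of 1000 random row sets were as high (median 0.02). The random rows were matched on signal alone and not on how genes vary together, so this share cannot count against less gonad. Tested over arrays without the neural list mean, the rise of the testis-raised rows had an exact permutation p of 9.14e-05. Values thus go both ways, and less gonad cannot be told apart from a change in the kind of germ cells. A difference in sex ratio or in the timing of gonad development between the groups stays open and untested, since the sex of the juveniles is unknown.

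In juveniles the neural list rose, most in heat-exposed trunk 1. Whole heads with the eyes included are argued against in heat-exposed trunks 1, 2, 3, 4, 5, 9 and 10 as a set, which lay above all controls in the neural list mean. The eye list had a median change of −0.0486 there and the neural list of 1.003. The SD of the eye median over resampled genes was 0.0674 (40 genes). It treats genes as independent and is not a spread of trunks. Within the set, trunks 2 and 10 stood 0.262 and 0.676 above the control mean in the eye list, where the highest control trunk stood 0.082 above it, so included heads stay open for these 2. Some tissue of the head could still be included: eye, forebrain and midbrain, and heart lists together had a median of 0.192 over 75 genes. The SD of this median over resampled genes was 0.0692. The median lay under the bound of 0.2, set before these values were known, by less than that SD. The heart list (0.65) and the forebrain and midbrain list (0.56) were higher. More nerve tissue of the trunk itself could not be decided, with a median of 0.11 in 9 spinal cord and peripheral nerve genes. A change of expression within nerve tissue stays open and was not tested.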

How the results depend on the processing

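The covariates of the neural and intestine lists, the fits without arrays that stand apart and the permutation tests of list means were chosen after the data were seen. In juveniles the 4579 genes became 1964 with an absolute log2 fold change of at least 1 (fewer genes can pass), 345 with the oocyte list mean as a covariate, 954 with the neural list mean and 2863 without heat-exposed trunks 1, 2 and 10. Both list means differed between the juvenile groups, so as covariates they take up part of the heat effect whatever its cause. In ovaries 0 genes in limma (3334 at an unadjusted p under 0.05) became 4 with array weights, 4869 with all arrays in 1 fit, where the spread is shared with other groups, and 8 without heat-exposed ovaries 2 and 4. In testes 20 became 8 with a repeated quantile normalization, 54 with array weights, 118 with an adjusted p under 0.1 and 11 with an absolute log2 fold change of at least 1. They became 102 with all arrays in 1 fit, 1 with the intestine covariate and 2 without heat-exposed testes 8 and 10, of which 1 was among the 20. Higher genes were 17 of the 20, 8 of the 8 and 51 of the 102. The interaction count of 380 became 20 with array weights, 1915 with an adjusted p under 0.1 and 2508 with all arrays in 1 fit. Beyond thresholds and sample numbers, the cause was not tested.

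Lists past the threshold numbered 0 in juveniles, 0 in ovaries and 1 in testes with an estimated correlation, and 0 in ovaries and 5 in testes in fry. In the permutation test of list means they numbered 0 in ovaries and 4 in testes. With 4 against 4 ovaries that test allows no p under 0.0286 before adjustment, so it could hardly pass a list there. Without heat-exposed ovaries 2 and 4 they numbered 2 in ovaries in camera. There the vitellogenin list, lower before without passing, was higher (adjusted p = 0.00594). The index difference was 4.04 in ovaries with rows chosen at the control temperature (adjusted exact permutation p = 0.0429) and 0.22 in testes with rows chosen in heat-exposed fish (adjusted permutation p = 0.0212). Each choice took rows extreme in 1 of the groups compared, which favours a difference. A common 75th percentile, with the rows of the index kept, cannot move the index difference by construction. The correlation of heat effects across genes became 0.207, 0.203 and 0.333 for juveniles and ovaries (Spearman's rho, dimmest rows left out, called rows only), 0.0444, 0.0657 and 0.143 for juveniles and testes, and 0.755 for ovaries and testes over called rows only. The value of 0.755 rests on the 20 rows called in testes, since the ovary called none, and these were selected on the testis effect. The median change of all genes in ovaries was −0.06, and −0.10 or −0.12 with a repeated quantile normalization or without the dimmest rows.

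Leaving out single arrays gave 3293 to 4919 genes in juveniles, 0 to 5 in ovaries, 1 to 57 in testes, 48 to 4817 for the interaction, and 16939 to 18616 and 7848 to 14212 between testis and ovary in control and heat-exposed fish. It gave 7 to 12 lists in juveniles, 9 to 18 in ovaries and 10 to 12 in testes, and index differences of 2.37 to 2.79, 2.43 to 5.01 and 0.03 to 0.14. Of single named genes, 33 of 121 in juveniles, 13 of 24 in ovaries and 10 of 24 in testes changed their call under some alternative.

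With the replicate number as a block, the testis count was 3 and the interaction count 106, both fewer, while 3209 genes passed in juveniles and 0 in ovaries, and no call of the index or count of lists changed by over 1.5 times. The numbers do not pair the arrays: correlations of same-numbered arrays ran from −0.0817 to 0.131 in juveniles, 0.0238 to 0.148 in ovaries and −0.0375 to 0.152 in testes, and 1 of 8, 3 of 4 and 4 of 10 controls correlated best with their own number.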

Other observations

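In the extracellular matrix list, which as a whole did not pass, 5 of 53 genes rose and 6 fell in juvenile trunks, the latter by 0.45 to 1.05 on the log2 scale. The genes col2a1a (9.91 ± 0.90 to 12.05 ± 0.89, SD, n = 8 and 10; limma adjusted p = 0.0017), matn1 (1.57), fmoda (1.37) and acana (1.14) rose, each by its log2 fold change. In the growth and thyroid list, which did not pass either, 2 of 40 rose, 5 fell and 33 did not pass. Among them igf1 (−1.0, adjusted p = 0.00503), igfbp3 (−0.91) and igfbp2a (−0.49) fell and igfbp5b (1.34, adjusted p = 0.000644) rose. In the glucocorticoid and stress axis list, which did not pass (camera adjusted p = 0.362), 1 of 26 rose and 4 fell. The glucocorticoid-responsive genes fkbp5 (−0.56) and tsc22d3 (−0.67) fell, and so did hsd11b2 (−0.90), which encodes the enzyme that inactivates cortisol. The gene that rose was cebpb (0.88).

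Among chromatin genes the histone methyltransferase gene suv39h1a (−1.97, adjusted p = 0.00904) and mbd3a (−0.55) fell in juveniles. In the heat shock and chaperone list, which did not pass (camera adjusted p = 0.767), 3 of 62 rose and 1 fell. Those that rose were hspa12a (0.55), chordc1 (chordc1b; 0.43) and cct2 (0.36), and fkbp5 (−0.56) fell. Higher too were fadd (0.60), mcl1a (0.50), gadd45bb (0.73) and gadd45gb.1 (1.14) of the apoptosis and DNA damage response and nfe2l2a (0.80), a regulator of the oxidative stress response. The vitellogenin gene vtg5 fell by 1.33. Members of marker lists also changed, but they were measured in whole trunks, so no single tissue was measured. Among muscle markers, mybpc2b (−0.90) and pvalb3 (−0.80) fell and tnni2a.4 (0.43) and atp2a1 (0.68) rose. Among epidermis markers, col17a1a (1.06) and cyt1l (0.87) rose and cdh1 (−0.93) and col17a1b (−0.83) fell. Among leukocyte markers, ighm (−0.85) and ccr7 (−1.13) fell and havcr1 (0.80) rose. Among exocrine pancreas markers, the transcription factor gene ptf1a rose by 1.19 and the amylase gene amy2al1 fell by 1.49. Among kidney markers, pax2a (0.73) rose and slc13a3 (−0.99) fell, and among intestine markers agr2 (0.41) rose and slc15a1a (−0.83) fell.

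Of the lists added after the data were seen, the heart list held 15 measured genes, of which 5 rose (median 0.65; adjusted exact permutation p of the list mean = 0.0364). The forebrain and midbrain list held 20, of which 4 rose (0.56; 0.0364), and the spinal cord and peripheral nerve list 9, of which 3 rose and 1 fell (0.11; 0.0369). The eye list held 40, of which 0 rose and 0 fell (−0.05; 0.648). Of the fixed lists, 14 oocyte genes lay among the 500 ovary-raised rows and 17 genes of the meiosis and spermatogenesis list among the 500 testis-raised rows.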
